A study of Mus musculus with 16 samples.

How the data were processed

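Total RNA from the left ventricle of WT and PPARalpha-deficient mice, 28 days after sham operation or TAC, was extracted with Trizol, labelled with biotin in one cycle and hybridised to Affymetrix Mouse Genome arrays with 45101 probe sets, per the labels' protocols and the series' design text. Each of the 4 groups held 4 arrays, assigned from the sample titles. The deposited values are linear signal intensity made with GCOS 1.4, per the submitters' processing notes. The deposited intensity of each array had been scaled to the same mean: the mean of the values between the 2nd and 98th percentiles was 500 on all 16 arrays. The algorithm settings, any filters and the detection calls are not given in the sources used here. Scaling of this kind sets the mean of each array, so a change shared by many bright genes moves all others the other way.

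The values were set to at least 11.9, the 10th percentile of all values, and log2 was taken with no further normalization, since the table was already scaled. Of the probe sets, 64 were controls, 34945 carried 1 gene symbol, 932 several and 9160 none in the array annotation. Of those with 1 gene, 34741 were matched by gene ID to a reference table of assembly GRCm38.p6 and 204 kept the annotation's symbol. Each of 18194 genes was represented by its probe set with the highest mean log2 signal over all arrays. The 40% of genes with the lowest mean were left out, which left 10916. Of the genes of the fixed lists and panel, 45 list genes had no probe set with that gene alone, and the panel genes Cpt1b and Spp1 are for that reason not analysed here. Acot1 fell below the filter on dim genes. No genome positions are given, since the files name no build.

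Limma 3.58.1 in R 4.3.3 was fitted to all 16 arrays with 1 coefficient per group, so that the groups shared 1 estimate of spread per gene, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 in a two-sided test. The comparisons were KO versus WT in sham and in TAC, TAC versus sham in WT and in KO, and the difference between the TAC responses (interaction). Standard errors are those of the moderated fit. The 15 gene lists and 13 marker lists, the panel of 30 genes and the rule for naming genes were fixed before the data were examined, as were the main settings and most alternatives. The rule named, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap, without unnamed transcripts (7 were skipped), up to 4 called members of each list or 2 with the smallest p, the panel, and the 5 genes with the smallest p where fewer than 5 were called. The text describes a part of the genes so named.

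Lists with at least 3 tested members, 24 of 28, were compared with other genes by camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera was repeated with a correlation estimated for each list, and fry was run as a self-contained test of direction. The calls that held with an estimated correlation were the fatty acid oxidation and the uptake lists in both genotype comparisons, the matrix and hypertrophy lists for TAC in KO and between genotypes in TAC, the oxidation and ion channel lists for TAC in KO, and the matrix list in the interaction.

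The steps were tested on simulated arrays with 200 of 10916 genes changed. At a 2-fold change, 78% were recovered for KO versus WT in sham, 79% for TAC in KO and 75% for KO versus WT in TAC. At 4-fold, 94%, 96% and 97% were recovered. There were 11, 6 and 4 false calls, and 7 for TAC in WT. With 1 list shifted by 0.5, camera called 0 of 23 other lists. Simulated genes varied independently, so this cannot show false calls that arise when genes of a list vary together. In the data, estimated correlations reached 0.529 for oxidative phosphorylation genes and 0.611 for cardiomyocyte markers.

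Alternatives were quantile normalization, centring each array on its median, other floors (38.4, the 25th percentile, or none), no filter or a 60% filter, all probe sets separately, the mean of a gene's probe sets, leaving out probe sets with _x_at or _s_at suffixes, limma with trend and robust, array weights, only the arrays compared, the replicate number as a block, and each array left out in turn. Added after the data were seen were fits without the 3 arrays with the most extreme spike-in signal (WT TAC replicate 3 and KO TAC replicates 2 and 3), with the mean signal of 9 spike-in probe sets as a covariate, and with the mean of 3 atrial markers as a covariate. Centring on medians moved the median of all genes to -0.12 for TAC in WT, 0.13 for TAC in KO, 0.22 for KO versus WT in TAC and 0.25 for the interaction, and to -0.03 for KO versus WT in sham. Without it, these medians lay within 0.03 of 0.

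Signal checks per array included the hybridisation spike-ins, the ratio of 3' to 5' signal of control transcripts and correlations. WT TAC replicate 3 stood apart, with a mean correlation of 0.94 with its group, a limma array weight of 0.425 and a spike-in signal of 1.45 relative to all arrays. KO TAC replicates 2 and 3 had 18S control signals of 2921 and 467.2, where the other arrays had 11470 or more. No 2 arrays shared more than 0.146% of values.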

Results

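Gene expression was measured in the left ventricle of wild-type (WT) mice and of mice lacking the nuclear receptor PPARalpha (KO), which activates genes of fatty acid use when lipid ligands bind it. Mice of each genotype underwent a sham operation or transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure, for 28 days. Each of the 4 groups (WT sham, WT TAC, KO sham and KO TAC) was represented by 4 Affymetrix arrays. The design asks which differences in cardiac expression go with PPARalpha at baseline and which do so under sustained load. All 16 arrays carried 45101 probe sets. Median signals lay between 108.3 and 163 after the authors' scaling, and mean correlations of an array with the others of its group lay between 0.94 and 0.969. The number of arrays per group limits the precision of every value. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples, which may be technical. Unless stated otherwise, a value is a log2 fold change ± its standard error from limma with 4 arrays per group, and adjusted p is the Benjamini-Hochberg value over 10916 genes.

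The targeted gene, Ppara, was examined first. Its representative probe set gave a mean log2 signal of 10.96 ± 0.26 (SD, n = 4) in WT sham, 10.76 ± 0.29 in WT TAC, 9.26 ± 0.21 in KO sham and 8.84 ± 0.21 in KO TAC, with no overlap between genotypes. Ppara was therefore lower by -1.70 ± 0.17 in KO sham (adjusted p = 5.71e-05) and by -1.92 ± 0.17 in KO TAC (adjusted p = 1.18e-05). The other 2 Ppara probe sets gave -1.23 ± 0.20 and -2.18 ± 0.25 in sham, and -1.38 ± 0.20 and -3.33 ± 0.25 in TAC, with standard errors from each probe set alone. Quantile normalization made the last of these the representative one, by a small margin in mean signal, and the value in TAC was then -3.30. The changes of all 3 with TAC in the knockout ranged from -0.42 to -1.37. Whether the probes lie in the deleted part of the gene is not known here, so the remaining signal of the knockout arrays says nothing about intact transcript.

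At baseline, the knockout ventricles had lower levels of transcripts for burning fatty acids. Of 21 tested genes of mitochondrial fatty acid oxidation, 11 fell and 0 rose over all genes, and 14 fell when adjusted over the list alone. Decr1, a reductase needed to oxidise unsaturated fatty acids, was 2.79-fold lower (-1.48 ± 0.11, adjusted p = 4.88e-06). Cpt2, which frees fatty acyl groups from carnitine inside mitochondria, was 2.49-fold lower (-1.32 ± 0.10, adjusted p = 5.4e-06; -0.82 with probe sets averaged), and Slc25a20, the carrier that brings acylcarnitines in, was 2.8-fold lower (-1.49 ± 0.23, adjusted p = 0.00491). The mean of the list was -0.65 ± 0.04 (SD, n = 4) in KO sham relative to the WT sham mean, against 0.07 for the SD of WT sham.

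Of 24 tested genes of fatty acid uptake, storage and peroxisomal oxidation, 5 fell and 0 rose, and 9 fell when adjusted over the list alone. Plin5, a coat protein of lipid droplets in oxidative tissues, was 6.13-fold lower (-2.62 ± 0.17, adjusted p = 1.25e-06). The peroxisomal enzyme Hsd17b4 (-0.66 ± 0.11, adjusted p = 0.0107) and the peroxisomal transporter Abcd3 (-0.74 ± 0.13, adjusted p = 0.00838) fell as well. The Abcd3 call was lost when its probe sets were averaged (adjusted p = 0.896) or arrays were centred on their medians (0.0921), and that of Hsd17b4 by centring (0.15), without _x_at and _s_at probe sets (0.0765) or with a fit to these 8 arrays alone (0.091), as was that of Slc25a20 (0.0633). Outside these lists, Fbp2, a muscle enzyme of gluconeogenesis, fell from a mean signal of 1040 to 69 (-3.91 ± 0.39, adjusted p = 5.52e-05). Fah, the last enzyme of tyrosine breakdown, was 4.01-fold lower (-2.0 ± 0.10, adjusted p = 6.22e-08), and the calcium-binding protein gene Tesc was 4.09-fold lower (-2.03 ± 0.17, adjusted p = 7.61e-06). The sodium channel subunit gene Scn4b was 2.7-fold lower (-1.43 ± 0.24, adjusted p = 0.00791).

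Fewer genes were higher in KO sham. Bex1 was 3.41-fold higher (1.77 ± 0.21, adjusted p = 0.000339), and Nnt, the mitochondrial transhydrogenase that makes NADPH, was 2.15-fold higher (1.10 ± 0.10, adjusted p = 3.2e-05). Aldh1l1, an enzyme of folate metabolism, was 2.28-fold higher (1.19 ± 0.16, adjusted p = 0.00153). Averaging the probe sets of a gene ended the calls of Nnt and Aldh1l1 (adjusted p = 0.568 for both). The labels do not give the strain, so for Nnt and the other genes a difference in strain background cannot be told apart from the knockout. The amino acid transporter gene Slc38a1 was 3.42-fold higher by its brightest probe set (1.78 ± 0.15, adjusted p = 1.43e-05), but gave -0.07 when probe sets with _x_at or _s_at suffixes were left out. Myot, a gene of the muscle Z-disc, was 1.87-fold higher (0.90 ± 0.16, adjusted p = 0.0125), a call lost with arrays centred on their medians (0.114) or without WT sham replicate 4 (0.054).

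In all, limma called 81 of 10916 genes between KO sham and WT sham, of which 25 were higher and 56 lower. With arrays centred on their medians, 7 were higher and 35 lower. Over all 10916 genes, 645 separated the groups without overlap, where chance gives 2.86% of genes. Of the 27 called genes that the naming rule took, 9 kept the call under every alternative and 16 without each array in turn. The fatty acid oxidation list (camera adjusted p = 4.8e-30) and the uptake and peroxisomal list (4.72e-11) passed with the preset correlation and with an estimated one (adjusted p = 0.000218 and 0.000133 with an estimated correlation). Macrophage markers were called higher (list median 0.29, adjusted p = 0.000269), but adjusted p = 0.232 with an estimated correlation. Cardiomyocyte markers (0.17, adjusted p = 0.00088) had adjusted p = 0.49 with an estimated correlation, and quantile normalization also ended that call (0.449). Interferon response genes (0.17, adjusted p = 0.0147) had adjusted p = 0.232 with an estimated correlation. Extracellular matrix genes were called lower (-0.06, adjusted p = 0.0358), with adjusted p = 0.513 with an estimated correlation, and lost the call without WT sham replicate 1 (0.409) or KO sham replicate 3 (0.195). The list of skeletal muscle markers, with 3 tested, was called higher, although Myot alone passed, 1 other member was positive and 1 negative (adjusted p = 0.0358; adjusted p = 0.232 with an estimated correlation), and the call was lost without WT sham replicate 1 or 4 or KO sham replicate 2 or 3 (adjusted p = 0.0519 to 0.0722).

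Of the 26 tested genes of the panel chosen before the data were examined, 3 passed in sham. Besides Ppara these were Ucp3, a mitochondrial uncoupling protein gene (-1.46 ± 0.29, adjusted p = 0.0239), and Pdk4, a kinase that shuts pyruvate out of oxidation (-1.16 ± 0.21, adjusted p = 0.0164). Ucp3 lost its call without WT sham replicate 2, 3 or 4 or KO sham replicate 2 (adjusted p = 0.0569 to 0.0739), and had 0.16 with a fit to these 8 arrays alone. Pdk4 lost its call without WT sham replicate 2, 3 or 4 or KO sham replicate 3 or 4 (adjusted p = 0.0534 to 0.0666), and had 0.171 with that fit. The 23 others ranged from -1.06 for the thioesterase gene Acot2 to 1.59 for Myh7, the fetal myosin heavy chain, with a smallest adjusted p of 0.138. Ppard and Pparg, the other PPAR isotypes, gave -0.42 ± 0.20 and 0.18 ± 0.29.

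**Figure D1:**
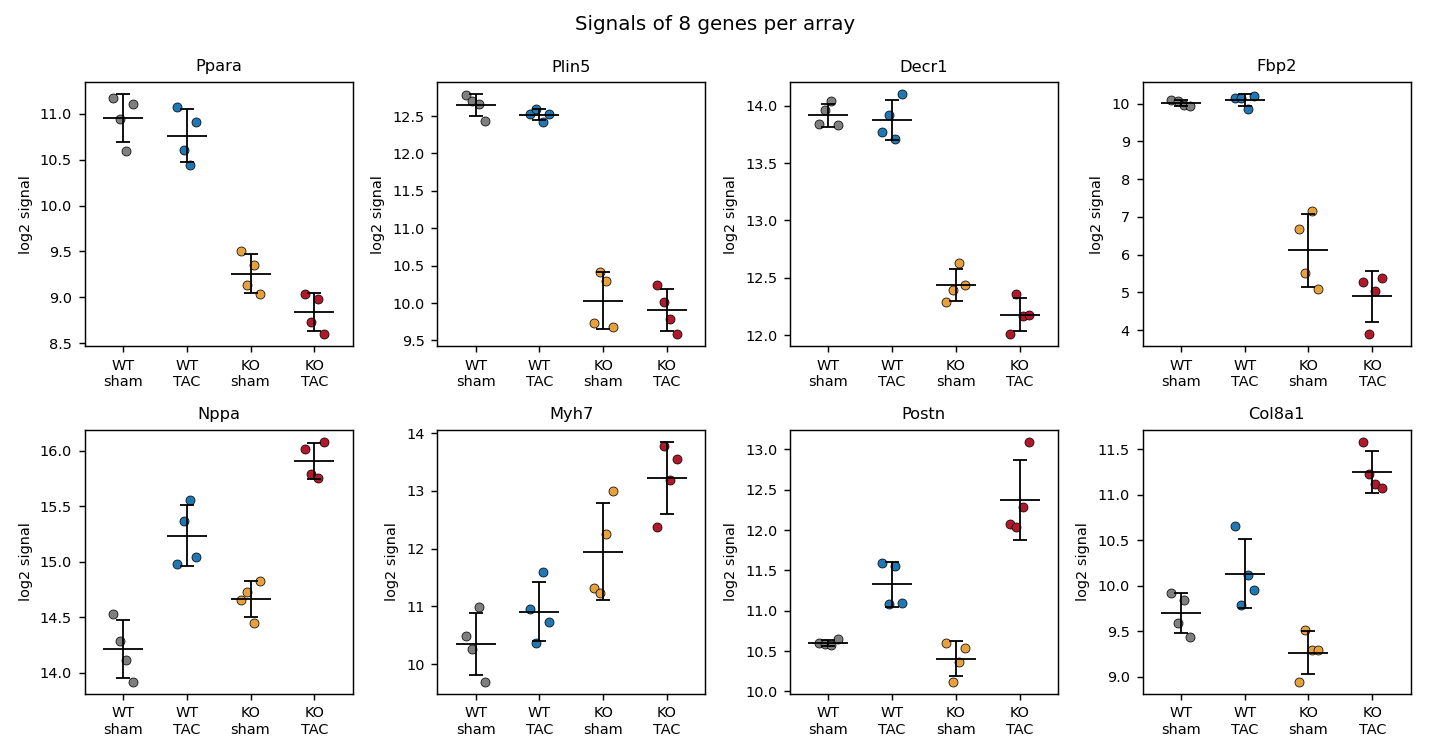
Log2 signal of 8 genes (vertical axes) on each of the 16 arrays, grouped as WT sham, WT TAC, KO sham and KO TAC (horizontal axes); points are arrays, long ticks are means and error bars are SDs (n = 4). Ppara, Plin5, Decr1 and Fbp2 separate by genotype without overlap, and the KO TAC arrays are the highest for Postn (12.37 ± 0.49) and Col8a1 (11.25 ± 0.23).

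In wild-type mice, no single gene passed the test after 28 days of pressure overload. Nppa, which encodes atrial natriuretic peptide and is reactivated in loaded ventricles, had the smallest adjusted p (1.03 ± 0.16, 2.04-fold, adjusted p = 0.107), with a mean log2 signal of 14.21 ± 0.26 (SD) in sham and 15.24 ± 0.28 in TAC. Other genes with the smallest p were Gpt2, an alanine aminotransferase gene (-1.04 ± 0.17, adjusted p = 0.128), the matrix proteoglycan gene Vcan (0.70 ± 0.13, adjusted p = 0.249), the phospholipid-binding protein gene Anxa5 (0.48 ± 0.09, adjusted p = 0.399) and Utp18 (-0.74 ± 0.16, adjusted p = 0.484). Of the panel, the skeletal actin gene Acta1 gave 0.91 ± 0.30, the brain natriuretic peptide gene Nppb 0.52 ± 0.16, the stretch-responsive gene Ankrd1 0.76 ± 0.17, and the matrix gene Postn 0.73 ± 0.21, none of which passed.

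The test on these arrays called 0 of 10916 genes with limma. At an unadjusted p under 0.05 there were 832 genes, where 546 are expected by chance, and the Nppa call depended on settings: limma with trend and robust called 1 gene, Nppa (adjusted p = 0.00441), and so did leaving out the dimmest 60% of genes (0.024). Without WT sham replicate 1 there were 2 calls, Nppa and Dlgap3 (adjusted p = 0.0316 for both), and without WT TAC replicate 3 there was 1, Shisa7 (-2.50, adjusted p = 0.00736). Dlgap3 and Shisa7 were singled out after their values were seen. On simulated data with the same arrays' spread, the fit recovered 85% of genes changed 2-fold and 95% of those changed 4-fold. In those data 200 genes were changed, which eases the adjusted threshold, and genes varied independently. Recovery of smaller or fewer changes was not simulated.

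As groups, hypertrophy and fetal genes (median 0.33, 15 of 17 positive, camera adjusted p = 5.83e-08) and extracellular matrix genes (median 0.27, 28 of 35 positive, adjusted p = 5.22e-06) were higher in WT TAC than other genes. Both calls were lost with an estimated correlation (adjusted p = 0.113 and adjusted p = 0.339 with an estimated correlation). When adjusted over the list alone, 5 hypertrophy genes and 3 matrix genes rose, against 0 over all genes. Cardiomyocyte markers (median 0.27, adjusted p = 1.29e-10) and oxidative phosphorylation genes (0.09, adjusted p = 3.1e-05) were called higher, with adjusted p = 0.339 and adjusted p = 0.469 with an estimated correlation. Quantile normalization ended the cardiomyocyte call (0.267) and turned the mean of the oxidative phosphorylation list to -0.06, as the spike-in signal as a covariate did (-0.01). The 21 fatty acid oxidation genes did not stand apart (median 0.02, adjusted p = 0.899).

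Smaller list calls in WT TAC were less firm. Interferon response genes were called higher (median 0.13, adjusted p = 0.0316; adjusted p = 0.344 with an estimated correlation), a call lost without WT sham replicate 2 or 3 or WT TAC replicate 1, 2 or 3 (adjusted p = 0.053 to 0.111). Immediate early genes were called lower (median -0.20, adjusted p = 0.0316; adjusted p = 0.442 with an estimated correlation), a call lost without WT sham replicate 1 (0.103) or WT TAC replicate 1 (0.378). The PPAR isotypes and partners were called lower (median -0.15, adjusted p = 0.0457; adjusted p = 0.344 with an estimated correlation), a call lost without WT sham replicate 1 or 4 or WT TAC replicate 2 or 3 (adjusted p = 0.0502 to 0.206). With the spike-in signal as a covariate, these 3 lists had adjusted p = 0.643, 0.643 and 0.737.

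In knockout mice, the same operation raised genes of the extracellular matrix and of the hypertrophic programme and lowered several genes of fatty acid oxidation. Of 35 tested matrix genes, 21 rose and 0 fell, and 27 rose when adjusted over the list alone. Cilp, a matrix protein of fibroblasts, rose 5.25-fold (2.39 ± 0.29, adjusted p = 0.000607), the short-chain collagen gene Col8a1 3.97-fold (1.99 ± 0.19, adjusted p = 0.000148), and the matricellular gene Postn 3.9-fold (1.97 ± 0.21, adjusted p = 0.000278). Ltbp2, which codes for a protein of elastic fibres, rose 4.94-fold (2.30 ± 0.35, adjusted p = 0.00284). The collagen gene Col3a1 (1.16 ± 0.18), the growth factor gene Ccn2 (1.77 ± 0.27) and the protease inhibitor gene Timp1 (1.92 ± 0.36) also rose. Without 3 arrays of extreme spike-in signal, the calls of Ltbp2 (adjusted p = 0.0537) and Timp1 (0.086) were lost. Timp1 also lost its call with a fit to the arrays of these groups alone (0.0881).

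Of 17 tested hypertrophy and fetal genes, 10 rose and 0 fell in KO TAC, and 14 rose when adjusted over the list alone. Acta1 rose 3.43-fold (1.78 ± 0.30, adjusted p = 0.00564), Rcan1, a calcineurin regulator and readout, 3.24-fold (1.70 ± 0.18, adjusted p = 0.000278), and Nppa 2.37-fold (1.24 ± 0.16, adjusted p = 0.000659). Fhl1, a LIM protein of stressed muscle, rose 2.12-fold (1.08 ± 0.15, adjusted p = 0.00165), though not when its probe sets were averaged (0.397). Myh7 (1.27 ± 0.42), Nppb (0.43 ± 0.16) and Ankrd1 (0.43 ± 0.17) did not pass. Among other called genes, Emp1, a membrane protein gene, rose 3.19-fold (1.67 ± 0.19, adjusted p = 0.000326; 0.296 with probe sets averaged), Mfap5 of fibroblast microfibrils 2.91-fold (1.54 ± 0.21, adjusted p = 0.00146) and the glycolytic enzyme gene Pfkp 1.87-fold (0.90 ± 0.11, adjusted p = 0.000659; 0.0583 with probe sets averaged).

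Fatty acid oxidation genes, already low in KO sham, fell further with TAC for 4 of 21 members over all genes and for 8 when adjusted over the list alone. Acaa2, the thiolase of the last step of the cycle, fell 1.69-fold (-0.76 ± 0.11, adjusted p = 0.0023), and the isomerase gene Eci1 1.45-fold (-0.54 ± 0.08, adjusted p = 0.00287). The calls of Etfb (-0.49 ± 0.10) and Hadh (-0.44 ± 0.09) were lost without KO sham replicate 2 or KO TAC replicate 2 or 3, and that of Etfb without KO sham replicate 4 also (adjusted p = 0.0563 to 0.0687). Ano10, of the anoctamin membrane proteins, fell 3.12-fold (-1.64 ± 0.18, adjusted p = 0.000278), Inmt, a methyltransferase gene, 2.18-fold (-1.12 ± 0.20, adjusted p = 0.00768), and the cytokine gene Il15 1.83-fold (-0.87 ± 0.12, adjusted p = 0.00221). Centring arrays on their medians, which moved the median of all genes in this comparison by 0.13, ended the calls of Eci1 (0.149), Etfb (0.237), Hadh (0.242) and Il15 (0.0546). Eci1 (0.0704) and Inmt (0.0548) also lost theirs without the 3 arrays of extreme spike-in signal. A fit to the arrays of these groups alone ended the call of Inmt as well (0.0634).

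Limma called 280 genes between KO TAC and KO sham, 173 higher and 107 lower, or 158 higher and 18 lower with arrays centred on their medians. Over all genes, 1176 separated the groups without overlap. Of the 36 called genes that the naming rule took, 11 kept the call under every alternative and 23 without each array in turn. The count was 157, 154 and 152 without KO sham replicates 2, 3 and 4, and 110, 141 and 182 without KO TAC replicates 2, 3 and 4. Of the 280 calls, 50 were still called without the 3 arrays with extreme spike-in signal, and 121 with that signal as a covariate. The first of these fits keeps only KO TAC replicates 1 and 4 of that group, so the smaller number of arrays alone could end calls. In both settings 100% of the 280 kept their direction with an unadjusted p under 0.05. Over these 280 genes, fold changes correlated with those of all arrays at 0.985 and 0.989. Picking genes for their change on largely the same arrays favours high values of both measures. Of the panel, 6 of 26 genes passed, and the 20 others ranged from -1.04 for Acot2 to 1.34 for the acute phase gene Serpina3n.

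The list calls that passed with both correlations were matrix genes (median 0.86, camera adjusted p = 2.24e-33, adjusted p = 0.00243 with an estimated correlation), hypertrophy and fetal genes (0.89, 8.41e-18, and adjusted p = 0.00243 with an estimated correlation), fatty acid oxidation genes (-0.20, 1.72e-07, and adjusted p = 0.0422 with an estimated correlation) and adult ion channel and calcium handling genes. The last list had a median of -0.26 with 16 of 17 members negative, although 0 members passed one by one over all genes and 1 fell when adjusted over the list alone (camera adjusted p = 3.59e-05, adjusted p = 0.0259 with an estimated correlation). Oxidative phosphorylation genes (median -0.23, 32 of 32 negative, adjusted p = 3.92e-11) had adjusted p = 0.218 with an estimated correlation, and 1 of them, Ndufv1, fell over all genes (-0.41 ± 0.09), a call lost without KO sham replicate 2 or 4 or KO TAC replicate 2 or 3 (adjusted p = 0.0698 to 0.0787) or with arrays centred on their medians (0.298). Tricarboxylic acid cycle genes (-0.21, adjusted p = 3.59e-05) had adjusted p = 0.118 with an estimated correlation, and 4 fell when adjusted over the list alone, against 0 over all genes. In the same arrays the mean actin 3'/5' signal ratio was 1.25 ± 0.08 (SD, n = 4) in KO TAC and 1.59 ± 0.11 in KO sham, and KO TAC replicates 2 and 3 had spike-in signals of 0.737 and 0.663 relative to all arrays.

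Among cell type markers in KO TAC, macrophage markers were called higher (median 0.24, 16 of 16 positive, adjusted p = 0.00174; adjusted p = 0.253 with an estimated correlation), but not without KO TAC replicate 1 (0.0584). Fibroblast markers (0.24, adjusted p = 0.0322; adjusted p = 0.27 with an estimated correlation) lost the call without KO sham replicate 2 or 3 or KO TAC replicate 1 (0.0575 to 0.16). Cardiomyocyte markers were called lower (-0.15, adjusted p = 0.0322; adjusted p = 0.593 with an estimated correlation), a direction that turned under quantile normalization, with a list mean of 0.05, and lost the call without KO sham replicate 2 or 4 or KO TAC replicate 2 or 3 (0.0646 to 0.262) and without the 3 arrays of extreme spike-in signal (0.821). Cell cycle genes (0.72, adjusted p = 0.00869; adjusted p = 0.132 with an estimated correlation), 3 of 10 of which rose when adjusted over the list alone, lost the call without KO sham replicate 3 (0.0624) or KO TAC replicate 1 (0.0589). Inflammatory genes (0.13, adjusted p = 0.0295; adjusted p = 0.27 with an estimated correlation) lost it without KO sham replicate 3 or KO TAC replicate 1 or 4 (0.0521 to 0.0965). Interferon response genes (0.14, adjusted p = 0.0322; adjusted p = 0.252 with an estimated correlation) lost it without KO sham replicate 1 or 2 or KO TAC replicate 1 or 4 (0.0633 to 0.13).

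**Figure D2:**
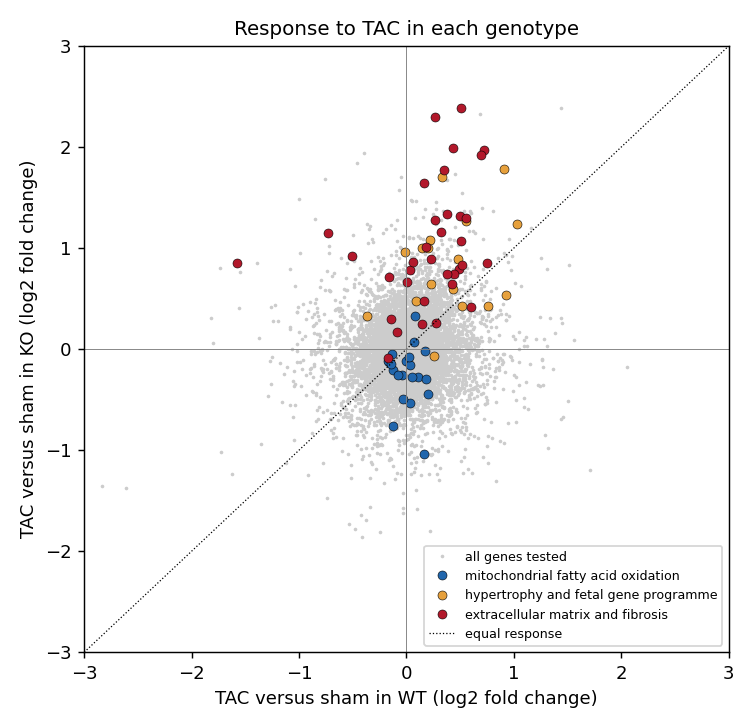
Log2 fold change of TAC versus sham for each of 10916 tested genes in WT (horizontal axis) and KO (vertical axis), with the 21 fatty acid oxidation, 17 hypertrophy and 35 extracellular matrix genes coloured. Of the matrix genes, 33 of 35 lie above the dotted line of equal response, with list medians of 0.27 in WT and 0.86 in KO.

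Under pressure overload, KO ventricles had lower levels of fatty acid transcripts than WT ventricles, as in sham, and higher levels of matrix and hypertrophy transcripts. Of 21 fatty acid oxidation genes, 18 were lower in KO TAC than in WT TAC and 0 higher, with 20 lower when adjusted over the list alone. Acot2 was 4.79-fold lower (-2.26 ± 0.28, adjusted p = 0.000376; -1.44 with probe sets averaged), Decr1 3.23-fold (-1.69 ± 0.11, adjusted p = 6.06e-07), and the medium-chain dehydrogenase gene Acadm 1.62-fold (-0.69 ± 0.09, adjusted p = 0.000352; 0.0611 with arrays centred on their medians). Of 24 uptake, storage and peroxisomal genes, 7 were lower over all genes and 12 when adjusted over the list alone, by which 1 was also higher. Plin5 was 6.13-fold lower (-2.62 ± 0.17, adjusted p = 6.06e-07) and Pex11a, which drives peroxisome division, 2.09-fold (-1.06 ± 0.15, adjusted p = 0.00153). Fbp2 was lower as well (-5.20 ± 0.39, adjusted p = 1.94e-06), but its mean signal of 30 in KO TAC lay under the 25th percentile of all values (38.4), so the size of the fall is uncertain. With the floor at that percentile, Fbp2 gave -4.80. Tesc (-1.89 ± 0.17), Scn4b (-1.80 ± 0.24) and Plbd1, a phospholipase-like gene (-1.75 ± 0.13), were lower too.

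Of 35 matrix genes, 14 were higher in KO TAC than in WT TAC over all genes and 21 when adjusted over the list alone, with 0 lower. Col8a1 was 2.17-fold higher (1.12 ± 0.19, adjusted p = 0.00497), Col3a1 1.88-fold (0.91 ± 0.18, adjusted p = 0.0135) and Postn 2.06-fold (1.04 ± 0.21, adjusted p = 0.0149), the last not without WT TAC replicate 4 (0.0519) or with a fit to these 8 arrays alone (0.133). Of 17 hypertrophy and fetal genes, 8 were higher over all genes and 10 when adjusted over the list alone. Myh7 was 4.98-fold higher (2.31 ± 0.42, adjusted p = 0.00853) and Rcan1 1.92-fold (0.94 ± 0.18, adjusted p = 0.0124). Nppa was 1.6-fold higher (0.67 ± 0.16, adjusted p = 0.0356), a call lost without any 1 of 7 arrays, all of these groups but WT TAC replicate 3 (adjusted p = 0.0548 to 0.104), and with a fit to these 8 arrays alone (0.128). With these included, the Nppa call was lost in 14 of 24 alternative settings. The calls of Col8a1, Col3a1, Postn, Myh7 and Rcan1 were all lost without the 3 arrays with extreme spike-in signal (adjusted p = 0.0501 to 0.111), while their values there were 1.19, 1.00, 1.33, 2.28 and 0.89. That fit has fewer arrays in both TAC groups, which alone could end calls. With the spike-in signal as a covariate, Myh7 (0.106), Rcan1 (0.16) and Col3a1 (0.0583) lost theirs too. Scores of the atrial markers Myl7, Myl4 and Sln moved with these groups as well, at 6.85 ± 1.90 (SD, n = 4) in WT TAC and 9.35 ± 1.4 in KO TAC, and with that score as a covariate Myh7 (0.0629), Col3a1 (0.0777) and Postn (0.0761) lost their calls, at values of 1.92, 0.85 and 1.00.

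Other called genes included the fast muscle light chain gene Myl1, 3.09-fold higher (1.63 ± 0.19, adjusted p = 0.00023), Myot, 2.5-fold higher (1.32 ± 0.16, adjusted p = 0.00032), and Wdfy1, an endosomal protein gene, 11.4-fold higher by its brightest probe set (3.51 ± 0.37, adjusted p = 6.97e-05) and 1.75 with probe sets averaged (adjusted p = 0.0272). Gpx3, a secreted glutathione peroxidase, was 1.77-fold higher (0.82 ± 0.11, adjusted p = 0.000949), and the chemokine gene Cxcl14 1.71-fold (0.78 ± 0.14, adjusted p = 0.00697; 0.185 with the spike-in signal as a covariate). Slc38a1 was 3.32-fold higher by its brightest probe set (1.73 ± 0.15), but gave -0.35 without _x_at and _s_at probe sets. Of 16 macrophage markers, 5 were higher over all genes and 6 when adjusted over the list alone. The complement gene C1qb was 1.56-fold higher (0.64 ± 0.10, adjusted p = 0.00428; 0.0542 with probe sets averaged and 0.0722 with a fit to these 8 arrays alone). Lgals3, which encodes galectin-3, was 1.93-fold higher (0.95 ± 0.21, adjusted p = 0.0267), a call lost without WT TAC replicate 3 or 4 or KO TAC replicate 1 or 4 (0.0617 to 0.0772) or with that fit (0.134).

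Limma called 268 genes between KO TAC and WT TAC, 144 higher and 124 lower, or 238 higher and 40 lower with arrays centred on their medians. Over all genes, 1043 separated the groups without overlap. Of the 55 called genes that the naming rule took, 13 kept the call under every alternative and 28 without each array in turn. The count was 175 and 146 without WT TAC replicates 2 and 4, and 135 and 133 without KO TAC replicates 2 and 3. Of the 268 calls, 53 were still called without the 3 arrays with extreme spike-in signal. With the spike-in signal as a covariate 70 were, and with the atrial score as a covariate 87. In these settings 97.8%, 96.6% and 100% of the 268 kept their direction with an unadjusted p under 0.05. Fold changes of the 268 correlated with those of all arrays at 0.988, 0.985 and 0.997. With arrays centred on their medians, 179 were still called and 90.3% kept direction at that p. Picking genes for their change on largely the same arrays favours high values of these measures. The fatty acid oxidation list (median -0.75, camera adjusted p = 4.62e-38) and the uptake list (-0.35, 2.52e-11) had adjusted p = 6.72e-05 with an estimated correlation. Matrix genes (0.71, 1.58e-16) and hypertrophy genes (0.64, 2.28e-10) had adjusted p = 0.0128 with an estimated correlation. The panel gave 10 calls among 26 genes, and the 16 others ranged from -0.43 for the calcium pump gene Atp2a2 to 1.19 for Serpina3n.

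Further list calls between the genotypes in TAC were lost with an estimated correlation. Macrophage markers (median 0.44, 16 of 16 positive, adjusted p = 1.47e-07) had adjusted p = 0.0766 with an estimated correlation. Oxidative phosphorylation genes (-0.28, 32 of 32 negative, adjusted p = 1.81e-16; adjusted p = 0.101 with an estimated correlation) had 1 lower member over all genes and 21 when adjusted over the list alone. Tricarboxylic acid cycle genes (-0.23, adjusted p = 1.11e-05; adjusted p = 0.0766 with an estimated correlation) had 1 and 6. Cardiomyocyte markers were called lower (-0.26, adjusted p = 1.11e-05; adjusted p = 0.231 with an estimated correlation), a direction that turned under quantile normalization (list mean 0.06) and a call lost with the spike-in signal as a covariate (0.676). Ion channel genes (-0.15, adjusted p = 0.00351; adjusted p = 0.0766 with an estimated correlation) lost the call under quantile normalization (0.105) or with probe sets averaged (0.226). Immediate early genes (0.24, 2 of 19 higher over all genes and 6 when adjusted over the list alone, adjusted p = 0.00199) had adjusted p = 0.185 with an estimated correlation.

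The remaining such calls also depended on single arrays. Interferon response genes (median 0.14, adjusted p = 0.0161; adjusted p = 0.179 with an estimated correlation) lost the call without WT TAC replicate 4 or KO TAC replicate 1 or 4 (0.0618 to 0.0906). Smooth muscle and pericyte markers were called lower (-0.33, adjusted p = 0.0275; adjusted p = 0.101 with an estimated correlation), but not without WT TAC replicate 1 or KO TAC replicate 1 or 4 (0.0523 to 0.0618). Inflammatory genes (0.15, adjusted p = 0.0282; adjusted p = 0.273 with an estimated correlation) lost the call without WT TAC replicate 1 or 4 or KO TAC replicate 1 or 4 (0.0643 to 0.157). Cell cycle genes (0.43, adjusted p = 0.0325; adjusted p = 0.185 with an estimated correlation) lost it without WT TAC replicate 3 (0.0649) or KO TAC replicate 1 (0.151).

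**Figure D3:**
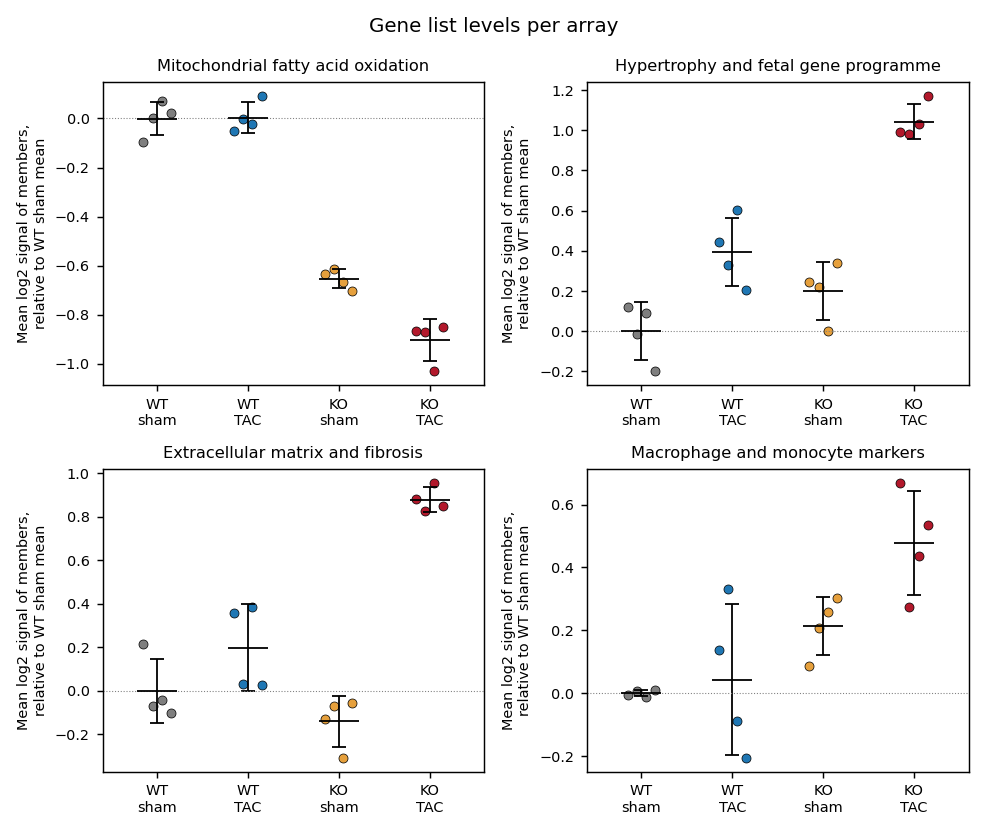
Mean log2 signal of the tested members of 4 gene lists on each array, relative to the WT sham mean (vertical axes), by group (horizontal axes); points are arrays, long ticks are means and error bars are SDs (n = 4). Fatty acid oxidation stands at -0.65 ± 0.04 in KO sham and -0.90 ± 0.08 in KO TAC, and extracellular matrix at 0.20 ± 0.20 in WT TAC and 0.88 ± 0.06 in KO TAC.

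Whether the response to TAC differed between genotypes was tested by the interaction. The matrix list rose more in the knockout, with an interaction median of 0.75 and 33 of 35 members positive (camera adjusted p = 8.9e-19, adjusted p = 0.0293 with an estimated correlation). Of its genes, 17 passed when adjusted over the list alone, against 0 over all genes. Col8a1 had one of the smallest p-values (1.56 ± 0.26, adjusted p = 0.125), and Postn gave 1.24 ± 0.29 and Ccn2 1.42 ± 0.39. The calcineurin readout Rcan1 (1.36 ± 0.25), the actin regulator Enah (0.85 ± 0.16), the cardiac homeodomain gene Hopx (-0.74 ± 0.13) and the matrix gene Efemp1 (-1.26 ± 0.22) had adjusted p = 0.125 as well.

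Limma called 0 genes for the interaction, with 1128 genes at an unadjusted p under 0.05 where 546 are expected by chance, and with 13 genes by limma with trend and robust. These 13 had adjusted p = 0.00644 to 0.0399. Bgn, Emp1, Rcan1, Gask1b, Lum, Enah, Col8a1 and Akap2 had positive values, and Eci1, Ano10, Hopx, Ech1 and Hadh negative ones. Leaving out WT TAC replicate 1 called Col8a1 (adjusted p = 0.0308), and leaving out KO TAC replicate 1 called Akap2 (1.17, adjusted p = 0.0312), a gene singled out after its values were seen. Calls of other lists were lost with an estimated correlation. These were hypertrophy genes (median 0.42, adjusted p = 5.41e-06), fatty acid oxidation genes (-0.19, 4.15e-06) and ion channel genes (-0.20, 0.00121), each with adjusted p = 0.0831 with an estimated correlation, of which 5, 7 and 1 members passed when adjusted over the list alone. Tricarboxylic acid cycle genes (-0.26, 6.47e-05) had adjusted p = 0.135 with an estimated correlation, oxidative phosphorylation genes (-0.34, 9.59e-17) adjusted p = 0.143 with an estimated correlation, and cardiomyocyte markers (-0.47, 1.43e-09) adjusted p = 0.145 with an estimated correlation. Quantile normalization ended the calls of the ion channel (0.191), tricarboxylic acid cycle (0.326), oxidative phosphorylation (0.544) and cardiomyocyte lists (0.904, with a list mean of 0.01). Immediate early genes (0.31, adjusted p = 0.0228; adjusted p = 0.386 with an estimated correlation) lost the call without WT sham, WT TAC or KO sham replicate 1 or KO TAC replicate 2 (0.0518 to 0.177) or with the spike-in signal as a covariate (0.699).

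Fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, called 4, 1, 9, 15 and 7 lists in KO versus WT sham, TAC in WT, TAC in KO, KO versus WT in TAC and the interaction. The list it called for TAC in WT was the hypertrophy list (adjusted p = 0.0198). In KO sham it called the clock list (median 0.31, adjusted p = 0.0396), which camera did not call (adjusted p = 0.0862).

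Set side by side across genes, the changes with TAC in WT and KO correlated at r = 0.10, and the knockout effects in sham and TAC at r = 0.21. Genes are not independent replicates, so no p-value is given, and the pairs of comparisons share no array. Of the 280 genes called for TAC in KO, 235 had the same sign in WT, a count without a test, over genes picked for their change in KO. Of the 81 genes called for the knockout in sham, 78 had the same sign in TAC. Of the 268 called for it in TAC, 203 had the same sign in sham. Both are likewise counts without a test, over genes picked for their change. Calls of both genotype comparisons shared 14 higher and 45 lower genes, where independent lists would share 0.33 and 0.64. With the spike-in signal as a covariate the correlations were -0.12 and -0.01.

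Several lists stood apart in no comparison by camera. In TAC versus sham in KO, glycolysis genes had adjusted p = 0.358, antioxidant genes 0.967, clock genes 0.0761, endothelial markers 0.138, atrial markers 0.491, Schwann cell markers 0.491 and sex chromosome genes 0.712. The median, mean and test of a list differed in sign for the tricarboxylic acid cycle, immediate early, endothelial and fibroblast lists in sham, Schwann cell markers for TAC in WT, skeletal muscle markers for TAC in KO and the interaction, glycolysis, PPAR partner and clock genes between genotypes in TAC, and interferon genes in the interaction. None of these list tests passed. The Y-linked genes Eif2s3y (signal 382 to 1240), Kdm5d (154 to 345) and Uty (164 to 295) had signal on all arrays.

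Markers of other cell types were mostly too dim to test. Of 8 adipocyte markers on the array 0 were tested, and Adipoq ranged in signal from 11.9 to 223. Of 11 lymphocyte markers, 2 were tested, Ighm (218 to 947) and Cd8a (187 to 592). Of 7 mesothelial markers 2 were tested, Krt8 (39.1 to 306) and Wt1 (46.3 to 283). The only tested red cell marker, Alas2, the first enzyme of haem synthesis in red cells, was 2.1-fold higher in KO TAC than in WT TAC (1.07 ± 0.22, adjusted p = 0.0189), a call lost without KO TAC replicate 2 (0.0658) and in 4 other settings, up to 0.348 with the spike-in signal as a covariate. Of 4 tested atrial markers, Myl7 (12.5 to 12100), Myl4 (235 to 8450) and Sln (11.9 to 5820) varied widely between arrays. The other, Nr2f2, ranged from 181 to 444. Among skeletal muscle markers, Myot ranged from 4730 to 16500, whereas Atp2a1 (53.3 to 332) and Mylpf (47.6 to 320) stayed low.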

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

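The test of WT TAC replicate 3, the test of a larger matrix response and the fit without 3 arrays were chosen only after the results were seen, and the spike-in covariate was added after the data were seen but before its own result was.

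The response of 8 gene lists to TAC differed between the genotypes by camera on the interaction. The list means were 0.821 for extracellular matrix, 0.446 for hypertrophy and fetal genes and 0.36 for immediate early genes, all higher in the knockout. They were -0.253 for fatty acid oxidation, -0.239 for the tricarboxylic acid cycle, -0.35 for oxidative phosphorylation, -0.215 for ion channels and -0.42 for cardiomyocyte markers. Of these, the matrix list alone held with an estimated correlation (adjusted p = 0.0293).

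TAC gave 280 calls in KO and 0 in WT, a difference in counts that is not itself a test. A weak array, WT TAC replicate 3, could hide a wild-type response, but without it the count in WT was 1, while the lowest count in KO without any 1 array was 110. Differences in array brightness could also produce the pattern, and with the spike-in signal as a covariate the interaction median of the matrix list was 0.815 against 0.749 without it. The same covariate lowered the KO count to 142. Of the 280 calls, 100% kept their direction with an unadjusted p under 0.05, a share that picking genes for small p on these arrays favours. A larger matrix response in the knockout goes with the interaction test of that list (adjusted p = 0.0293 with an estimated correlation). No single gene passed in the main fit. Limma with trend and robust called Col8a1 (adjusted p = 0.0138), Lum (0.0138) and Bgn (0.0168) of that list.

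Dixon's test was run on list scores, on log2 signals of the panel and of genes named in the text, and on measures per array. Of 536 groups of 4 arrays, 30 held an array far from the other 3 relative to the range of that group, where 27 are expected by chance at 1 in 20. The differences themselves could be small, as for Hopx in KO TAC (14.7 against 14.6) and Eci2 in WT sham (13.1 against 13). Of list scores relative to WT sham, KO TAC replicate 3 stood at -1.03 for fatty acid oxidation, WT TAC replicate 1 at -0.2 for the clock, and WT TAC replicate 4 at -0.0496 for fibroblast markers. The actin 3'/5' signal ratio was 1.75 on KO sham replicate 4. The other 26 were log2 signals. In WT sham, replicate 1 stood apart for Pdk4 (13.9), Ccne1 (6.73), Gpt2 (9.16), Col1a1 (10.5) and Cycs (16), replicate 2 for Eci2 (13.1) and replicate 3 for Bex1 (9.89). In WT TAC, it was replicate 1 for Ucp3 (9.56), replicate 3 for Pfkp (10.6), Scn4b (8.64) and Cd36 (14.2), and replicate 4 for Ltbp2 (8.28) and Rab4a (6.38). In KO sham, it was replicate 1 for Gsta4 (12.6) and Slc38a1 (10.1), replicate 2 for Eci1 (14), Ucp3 (7.22) and Hadh (16.1), replicate 3 for Angptl4 (8.04) and Cycs (15.9), and replicate 4 for Ankrd1 (15.8). In KO TAC, it was replicate 2 for Lum (13.1) and Col3a1 (13.3), replicate 3 for Acot2 (9.33) and Uck2 (11), and replicate 4 for Hopx (14.7).

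Probe sets without a gene in the array annotation, which entered no comparison of genes, held signal as well. Of 3811 such probe sets above the filter, limma called 6 between KO and WT in sham, 14 between TAC and sham in KO and 23 between KO and WT in TAC. Of 614 probe sets listed with several genes, it called 4, 1 and 7.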

How the results depend on the processing

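Lists were not tested over all probe sets or with only the arrays compared. The fits without 3 arrays, with the spike-in signal and with the atrial score as a covariate were chosen after the data were seen. Over the alternatives that gave a list value, the lists that were called kept direction and side of the threshold 999 times, lost the call 112 times and turned 6 times; calls gained by other lists show only in the counts of lists below. Values of named genes, called or not, stayed on their side of the threshold 4921 times, lost a call 661 times and turned 2 times, and 36 gained a call. These counts pool called genes with panel genes that had no call to lose, so they understate how often called genes lost theirs. Of 2816 values of panel genes that were not called, 120 had the opposite sign and still no call, and are counted as unchanged. Apart from the numbers of tested genes and arrays, the cause was not tested.

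KO versus WT in sham gave 81, but 42 with arrays centred on medians (7 higher and 35 lower, against 25 and 56) and 38 with only the arrays compared. TAC in WT gave 0, but 1 with a 60% filter, 1 with trend and robust and 1 without 3 arrays. TAC in KO gave 280, but 176 with median centring (158 higher and 18 lower, against 173 and 107), 117 with no filter, 122 with probe sets averaged, 426 with trend and robust, 79 with only the arrays compared, 55 without 3 arrays and 142 with the spike-in covariate. KO versus WT in TAC gave 268, but 121, 125, 424, 66, 56 and 85 under the last 6 of these and 89 with the atrial covariate. Its split was 238 higher and 40 lower with median centring, against 144 and 124. The interaction gave 0, but 1 with no filter, 1 with probe sets averaged and 13 with trend and robust. Without each array in turn, the counts ranged from 55 to 74, 0 to 2, 110 to 274, 133 to 244 and 0 to 1 in the order above.

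The correlation of TAC responses was 0.103 (jackknife SE 0.0642), but 0.0207 with no filter, 0.2 with a 60% filter, 0.0286 over all probe sets and -0.12 with the spike-in covariate. That of knockout effects was 0.211 (jackknife SE 0.0587), but 0.0604, 0.284, 0.0948 and -0.0149. Without each array they ranged from 0.0599 to 0.125 and from 0.172 to 0.226.

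Camera called 7 lists in sham, but 4 with a 60% filter, 4 with the spike-in covariate and 2 with an estimated correlation, and fry called 4. For TAC in WT it called 7, but 4 with the spike-in covariate and 0 with an estimated correlation, and fry called 1. For TAC in KO it called 12, but 4 with an estimated correlation. Between genotypes in TAC it called 14, but 4 with an estimated correlation. For the interaction it called 8, but 3 with quantile normalization and 1 with an estimated correlation. Without each array it called 5 to 9, 5 to 9, 7 to 13, 10 to 15 and 7 to 10 lists. The mean of oxidative phosphorylation for TAC in WT turned to -0.0558 with quantile normalization and -0.0136 with the spike-in covariate. That of cardiomyocyte markers turned to 0.0493 and 0.0353 for TAC in KO, and with quantile normalization to 0.0572 between genotypes in TAC and 0.0118 in the interaction. Slc38a1 turned to -0.071 in sham and -0.348 in TAC without _x_at and _s_at probe sets. With median centring, the median of fatty acid oxidation in the interaction was 0.0606, with the test still lower (adjusted p = 0.00483).

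With the replicate number as a block, the counts were 64, 0, 220, 187 and 0, of which 63, 197 and 174 were calls of the fit without the block. Same-numbered arrays had a mean correlation of 0.00939 in deviations from group means (-0.185 to 0.137), over 0.1 in 5 of 24 pairs. This gives no sign that the numbers pair the arrays, but cannot exclude a small shared effect. Signal near the floor of 11.9, which held 6.07% to 13.4% of values per array, limits what dim genes can show.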

Other observations

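The tests of genes that neighbour Ppara and the fit without 3 arrays were chosen only after the results were seen, and the atrial covariate was added after the data were seen but before its own result was.

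Antioxidant genes moved in both directions with TAC in KO. Of 20 tested, 2 rose and 1 fell over all genes, and 3 rose and 2 fell when adjusted over the list alone, so that camera saw no common direction (adjusted p = 0.967) while fry for either direction passed (3.22e-09). That fry test does not single out antioxidant genes, since other lists passed it in this comparison. Glycolysis genes had adjusted p = 5.35e-08 by it, with 2 higher and 4 lower when adjusted over the list alone, and matrix genes had 3.22e-09. Gpx3 rose (0.59 ± 0.11, adjusted p = 0.0121), and Gstm1, a glutathione transferase gene, fell (-0.59 ± 0.09, adjusted p = 0.00284). Both calls were lost with a fit to these 8 arrays alone (0.0766 and 0.0501) and without the 3 arrays of extreme spike-in signal (0.106 and 0.0673), and that of Gstm1 with arrays centred on their medians (0.0824). The cytokine gene Il15 was the single member of 28 inflammatory genes called in that comparison.

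Genes near Ppara could differ because DNA of the donor strain was carried over around the targeted locus. Of the 50 tested genes on either side of Ppara in assembly GRCm38.p6, 2 of 100 were called in sham, Chkb (-0.58 ± 0.09) and Slc38a1, against 78 of 10815 others (odds ratio 2.81, 95% interval 0.33 to 10.8, Fisher's exact p = 0.167). In TAC, 7 of 100 were called against 260 others (odds ratio 3.06, 1.18 to 6.64, exact p = 0.0112), among them Chkb (-0.86 ± 0.09), Gramd4 (-0.61 ± 0.13) and Cdpf1 (-0.70 ± 0.16). Kif21a (-0.54) and Gm17546 (-1.20) were lower too, while Slc38a1 (1.73) and Xrcc6 (0.415) were higher. Without _x_at and _s_at probe sets Slc38a1 gave -0.07 in sham and -0.35 in TAC, so its place in both counts is uncertain. The sham test cannot tell, and the TAC test leaves room for a local effect of the locus for a few genes. Neighbours made up 2.47% of the sham calls, so such DNA near Ppara could explain few of them. The labels used here do not give the strain, and differences in strain background away from Ppara were not tested.

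The levels of atrial markers differed by array within each group. Over deviations from group means on 16 arrays, Myl4 and Sln each correlated with Myl7 at r = 0.946 (Spearman 0.947 and 0.964, permutation p = 1e-05, the smallest possible with 1e+05 resamples), and at 0.941 and 0.926 without the 2 most extreme arrays. Noise of single probe sets would not move 3 genes together, and atrial tissue in some samples could. Of 8 atrial markers on the array, 4 were tested, these 3 and Nr2f2. The 3 were highest on KO sham replicate 4, but Nr2f2 (signal 181 to 444) was highest on KO TAC replicate 1. Correlations of the 3 chosen genes alone therefore cannot tell atrial tissue from another shared change of these genes. Such tissue could drive the TAC calls in KO. With the atrial score as a covariate, 195 of the 280 calls were still called, and 100% kept their direction at an unadjusted p under 0.05. Picking genes for small p on these arrays favours that share, so it cannot tell whether atrial tissue contributes. The score was 10.57 ± 1.93 (SD, n = 4) in KO sham and 9.35 ± 1.4 in KO TAC, a difference smaller than either SD. Between genotypes in TAC, 87 of 268 calls were still called with this covariate, so a part played by atrial tissue there stays open.

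Other splits of the same arrays tested how many calls arise when arrays are grouped at random, with a fit to the 8 arrays alone. The true groups had the highest count in 1 of 35 splits for KO versus WT in sham (38, highest other 2), 1 of 35 for TAC in KO (79, highest other 0) and 1 of 35 for KO versus WT in TAC (66, highest other 1). For TAC in WT and for the interaction the true count was 0, which all 35 splits (highest other 1) and all 100 reassignments of genotype (highest other 3) reach by construction, so these say nothing of chance.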
